A study of Gallus gallus with 18 samples.

How the data were processed

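The deposited table gives FPKM and whole-number estimated counts for 23741 chicken genes in 18 libraries. Per the labels, poly(A) RNA was caught on oligo-dT beads, fragmented and copied with random hexamers, and paired ends were read on an Illumina NovaSeq. No strand marking is stated, so overlapping genes on opposite strands cannot be parted. The authors' processing notes name cutadapt, HISAT2 and StringTie. Their versions, order and settings are not given in the sources used here, nor is the genome build. The reads were not analysed here, so mapping, the counting of reads that match several genes, and FPKM are the authors' steps. Coordinates are those of the deposited table. A GRCg7b gene table served for symbols and chromosome names only, matching 19402 gene IDs.

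The FPKM values are relative to each library's total count, including 37 nuclear rRNA genes. These genes took very different shares of the libraries, so all FPKM of an rRNA-rich library are pressed down. For that reason the test used here is edgeR's quasi-likelihood test on the estimated counts with TMM scaling, 1 mean per group and contrasts between groups. The design fixed before the data were examined had named limma on log2(FPKM + 1). Because the table holds counts, which call for a count model, the order was changed after the files were opened, and limma on FPKM runs as an alternative.

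Each fit takes only the libraries of its comparison: 6 for each diet comparison and for control livers by age, 12 for the difference of diet effects between rooster and offspring liver. A gene is tested when FPKM is at least 1 in at least 3 libraries of the fit. A gene counts as called, and is said to rise or fall, when its Benjamini-Hochberg adjusted p is below 0.05. Unless another test is named, adjusted p for a gene is that of edgeR and for a list that of camera. Fold changes are FE minus FCON in log2, and SE is the standard error of the log2 value. Expression is given in TMM-scaled CPM, mean ± SD of 3 libraries per group. Replicates are, as labelled, different birds or pools, so p measures spread between these few libraries only.

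Where 1 group has 0 counts, the fold is given as a lower bound from an assumed 3 counts over that group. Such floors and the Wilson 95% intervals of single libraries cover counting error only. The medians of gene lists keep their value when such genes are set at their bound.

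There are 39 lists written before the values were examined: 21 of pathways and 18 of cell types. Of their symbols 889 matched by the name in the deposited table, 17 by the reference symbol and 124 not at all. A match through older synonyms was dropped after the list results had been seen, because it had put wrong genes in lists. With synonyms, offspring liver also passes fatty acid oxidation (0.0459 instead of 0.0535) and cholesterol synthesis (0.0353 instead of 0.0719), and no other call differs. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01. Camera asks whether members move relative to all other genes. A correlation estimated from the residuals is given beside each result, and fry, which compares a list with 0, is a second test.

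Genes are named by a rule fixed in advance. It takes the 8 largest rises and falls in log2(FPKM + 1) among called genes with a symbol, at least 2 FPKM and no overlap between groups. Where no gene is called, it takes the 5 smallest p in each direction, and these are not said to change. It adds members of lists that pass, of which the 2 with the smallest p are named here, and 17 panel genes of lipid, one-carbon and methylation biology (2 more panel genes of the rule are not reported here). The panel genes called in the difference of diet effects are named there too.

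Sperm libraries with the same number in FCON and FE correlate with each other after removal of group means (0.119, 0.179 and 0.243, all above 0.1), so the numbers may pair them. With number as a block sperm gives 0 genes and 5 lists, and no call changes.

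Alternatives comprise 13 planned settings, 8 settings added after the data were seen, and 18 fits without 1 library each. The added settings cover other tools, scalings and gene sets. All splits of the same libraries into false groups were run for each comparison of 2 groups, and for the difference of diet effects 100 splits were taken, the real one and others drawn at random.

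A self-test ran on simulated negative binomial counts with the means, library sizes and spread of each fit, in which 100 genes changed 2-fold and 100 genes 4-fold. The share recovered was 19% and 77% for rooster livers, 1% and 34% for offspring livers, 0% and 0% for sperm, 0% and 22% for the difference of effects, and 3% and 55% for control livers. The false calls were 6, 5, 0, 2 and 3. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.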

Results

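The series holds polyA RNA-seq of Arbor Acres broiler breeders fed 0.25 (FCON) or 5 (FE) mg folic acid per kg of feed. Its 18 libraries form 6 groups of 3, as labelled: liver of roosters at 35 weeks, liver of their day-old offspring, and sperm. Each offspring library is a pool of 4 chicks, and sperm FE replicate 3 is labelled 36 weeks where the others are labelled 35. Library totals run from 17 M to 43.1 M estimated counts (M, mega), with 40.1 ± 3.59 M in rooster FCON and 20.3 ± 3.02 M in rooster FE.

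The rooster libraries differ in more than diet. Genes of the W chromosome, which only hens carry, took 1065 ± 51.0 CPM (for W genes of the plain library total) in the libraries labelled rooster FCON and 1.16 ± 1.06 in those labelled rooster FE. Z genes were lower relative to autosomal genes in rooster FCON (mean log2 difference -0.325 ± 0.00622 over 149 Z and 4181 autosomal genes) than in rooster FE (0.187 ± 0.0849). Nuclear rRNA took 6.43 ± 3.02% of rooster FCON and 45.9 ± 13.9% of rooster FE counts, and mitochondrial rRNA 0.57 ± 0.131% and 6.07 ± 0.870%. Every rooster liver difference below therefore sets the libraries labelled FE, with hardly any W counts, against the libraries labelled FCON, with at least 1015 CPM of them. In offspring, the pools numbered 2 held 963 (FCON, Wilson interval 950 to 976) and 1299 (FE, 1288 to 1310) CPM of W genes. The other 4 pools held between 2.59 (2.09 to 3.22) and 9.34 (8.13 to 10.7). Offspring nuclear rRNA was 24.5 ± 7.02% in FCON and 13 ± 7.89% in FE. In sperm it was 10.7 ± 6.10% and 19.5 ± 26.7%, with 50.2% in FE replicate 2.

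**Figure D1:**
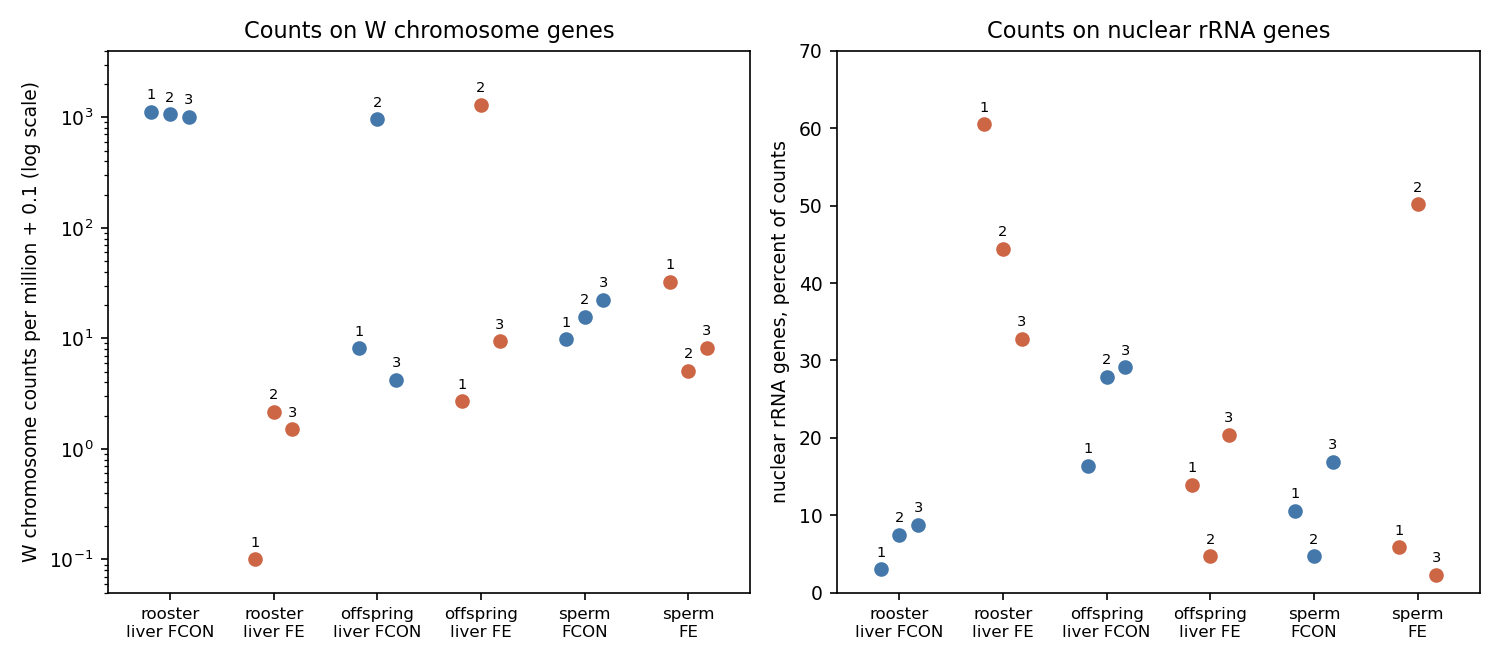
CPM of W chromosome genes plus 0.1 (log axis) and nuclear rRNA in % of all counts, for each of the 18 libraries. Digits are replicate numbers, blue is FCON and orange is FE.

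In the libraries labelled rooster liver, most genes that make cholesterol, and several that turn it into bile acids, were lower in FE than in FCON, and single ones were nearly silent. SQLE, which opens the sterol branch of the pathway, went from 40.6 ± 1.93 to 0.517 ± 0.101 CPM, and CYP7A1, the first enzyme of bile acid synthesis, from 84.4 ± 1.46 to 0.538 ± 0.721. FABP1, the liver's fatty acid carrier, fell from 427 ± 1.99 to 2.22 ± 1.96, and the nuclear genes of oxidative phosphorylation fell as a list. Macrophage genes such as the scavenger receptor MARCO rose as a list, and lymphocyte and heat shock lists did too, though these calls are lost with an estimated correlation (adjusted p = 0.0925 for T and NK cells, 0.108 for B and plasma cells and for heat shock). These same libraries differ in W counts, in nuclear rRNA (45.9% in FE, 6.43% in FCON) and in hepatocyte markers (14 of 18 fell), so diet, sex and origin of the birds, RNA quality and the share of hepatocytes cannot be told apart for any of these genes.

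Of 22 tested cholesterol synthesis genes 17 fell and 1 rose (19 and 1 adjusted over the list alone, median log2 -2.54, adjusted p = 5.43e-19, and adjusted p = 0.0336 with an estimated correlation). SQLE (gene 420335, chromosome 2, 138683095 to 138697225) fell by 6.31 log2 (SE 0.18) and the C4 demethylase MSMO1 by 4.30 (SE 0.12), both at adjusted p = 7.23e-06. Bile acid and sterol export genes fell in 9 of 14 and rose in 1 (10 and 1 over the list alone, adjusted p = 0.00324, adjusted p = 0.108 with an estimated correlation). CYP7A1 (gene 414834, chromosome 2, 112027114 to 112034638) held 19 counts in FE and 14053 in FCON, a fall of 7.52 log2 (SE 0.73, adjusted p = 3.62e-04). CYP8B1, which sets the ratio of bile acids, fell from 346 to 5.82 CPM, and the bile salt pump ABCB11 fell by 1.56 log2 (adjusted p = 1.67e-04). Lipoprotein genes fell in 7 of 12 with 0 rises (8 and 1 over the list alone, adjusted p = 9.74e-05, adjusted p = 0.2 with an estimated correlation). Among them were the plasma cholesterol esterifier LCAT (-1.60) and SAR1B (-2.27), which carries lipoproteins out of the endoplasmic reticulum.

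In the libraries labelled FE, fatty acid synthesis genes fell in 13 of 25 and rose in 5 (13 and 6 over the list alone, adjusted p = 0.00127, adjusted p = 0.153 with an estimated correlation, and 0.0540 without FCON replicate 3). The elongase ELOVL2 had 73.3 CPM in FCON and 0 counts in FE, at least 1070-fold lower, and the carboxylase ACACB fell by 2.79 log2. Triglyceride and lipid droplet genes fell in 7 of 13 and rose in 1 (the same over the list alone, adjusted p = 0.00286, adjusted p = 0.108 with an estimated correlation). The droplet coat gene PLIN1 went from 27.4 CPM to 0, at least 401-fold lower, and GPAM, which starts glycerolipid assembly, fell by 1.10. Fatty acid oxidation fell in 16 of 28 and rose in 3 (17 and 3 over the list alone, adjusted p = 0.00115, adjusted p = 0.0925 with an estimated correlation), with the peroxisomal enzymes ACAA1 (-1.90) and EHHADH (-1.22). PPAR signalling fell in 22 of 50 and rose in 9 (22 and 10 over the list alone, adjusted p = 0.00607, adjusted p = 0.130 with an estimated correlation). It contains ACAA1, the acyl-CoA synthetase ACSL1 (-1.66) and FABP1 (gene 374015, chromosome 4, 85982308 to 85986038, log2 -7.68, SE 0.57, adjusted p = 1.28e-04).

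Of the 17 panel genes 15 were tested in rooster liver, all but PPARG and METTL4. SCD (2.70, SE 0.52, adjusted p = 0.00663), the lipase PNPLA2 (1.36, SE 0.08, 6.86e-05) and MAT1A (0.85, SE 0.23, 0.0224) rose. MAT1A lost its call without any 1 FCON replicate or FE replicate 3 (adjusted p up to 0.0849), and turns negative in FPKM. The lipogenic regulator SREBF1 (-1.82, adjusted p = 0.00388), CPT1A (-2.04, 0.00146) and LPL (-2.50, 0.00141) fell. So did BHMT (-1.93, 1.17e-05), which remethylates homocysteine without folate, from 2096 to 549 CPM, and DNMT1 (-1.55, 2.00e-04). Not called were ACACA (0.78, adjusted p = 0.262), FASN (-0.26, 0.170), PPARA (-0.17, 0.779), MTR (-0.21, 0.355), SHMT1 (-0.48, 0.0893), N6AMT1 (-0.08, 0.826) and ALKBH1 (0.19, 0.537), which is called lower with FPKM set to equal sums (-0.76, 0.0408). Leaving out 1 library brought in ACACA (without FCON 3, 0.00459) and, without FE 1, FASN (0.00834), SHMT1 (0.00220) and PPARA (0.00786).

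Genes that mark hepatocytes fell in 14 of 18 and rose in 2 (the same over the list alone, adjusted p = 1.70e-07, adjusted p = 0.329 with an estimated correlation). SERPINC1, the thrombin inhibitor, went from 1312 to 170 CPM and the plasma glycoprotein AHSG from 2548 to 293, while its relative FETUB fell by 3.90 log2. Xenobiotic metabolism fell in 17 of 35 and rose in 5 (18 and 5 over the list alone, adjusted p = 6.73e-05, adjusted p = 0.0621 with an estimated correlation), with CYP2AC1 (-3.30) and CYP1A1 (-3.46), each with near copies that reads may not part. Nuclear genes of oxidative phosphorylation fell in 33 of 48 with 0 rises (36 over the list alone, adjusted p = 1.61e-07, adjusted p = 0.0367 with an estimated correlation), among them NDUFB5 of complex I (-2.07). The W gene ATP5A1W in this list (gene 431564, 1391533 to 1453513) went from 250 ± 12 CPM to 0, at least 3630-fold lower. HINTW (gene 395423, W, 1839400 to 1896965), which has many copies, went from 172 ± 2.79 to 0, at least 2510-fold lower. The lysozyme gene LYG2 (-5.74) and SELENOI of phospholipid synthesis (-4.66) complete the 8 falls that rank first by log2(FPKM + 1). Interferon response fell in 16 of 32 and rose in 3 (the same over the list alone, adjusted p = 4.06e-05, adjusted p = 0.130 with an estimated correlation), with IFI6 (-2.78) and USP18 (-2.35). Cell cycle genes fell in 9 of 18 (9 over the list alone, adjusted p = 0.0247, adjusted p = 0.136 with an estimated correlation, and up to 0.261 without any 1 FCON replicate), with RRM2 (-2.41) and TOP2A (-2.84).

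CAMK1D, a calcium-dependent kinase (gene 425522, chromosome 1, 6924139 to 7144552), rose from 10.6 ± 0.526 to 985 ± 142 CPM (log2 6.54, SE 0.15, adjusted p = 3.32e-06). The oxygen-sensing factor EPAS1 (gene 395596, chromosome 3, 26671415 to 26748494) rose from 46.4 ± 3.56 to 847 ± 204, and CTSD, a lysosomal protease (gene 396090, chromosome 5, 14320715 to 14331883), from 5.87 ± 0.268 to 157 ± 35.5. The other rises that rank first by log2(FPKM + 1) were CNN1 of smooth muscle (5.42), the small heat shock gene HSPB9 (4.47), IGLL1 (4.09, an immunoglobulin light chain whose copies reads may not part), COTL1 of the actin skeleton (3.92) and UGP2 of glycogen synthesis (3.54). Macrophage genes rose in 11 of 14 with 0 falls (11 over the list alone, adjusted p = 4.12e-08, adjusted p = 0.0367 with an estimated correlation). MARCO (gene 395488, chromosome 7, 28482901 to 28491944) went from 12.6 ± 0.709 to 109 ± 4.39 CPM (adjusted p = 8.28e-06), and C1QC rose by 1.81 log2. T and NK genes rose in 7 of 8 (7 over the list alone, adjusted p = 1.13e-04, adjusted p = 0.0925 with an estimated correlation), with GNLY (2.10) and CD3D (1.68). B and plasma cell genes rose in 4 of 5 and fell in 1 (the same over the list alone, adjusted p = 2.51e-04, adjusted p = 0.108 with an estimated correlation), including IGLL1 and BTK (1.61), a kinase that myeloid cells also use. Leukocyte genes, some of them shared with the macrophage and T cell lists, rose in 6 of 11 (6 over the list alone, adjusted p = 0.00376, adjusted p = 0.135 with an estimated correlation), with RAC2 (1.72) and SPI1 (2.50).

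Heat shock genes rose in 14 of 21 and fell in 2 (15 and 2 over the list alone, adjusted p = 9.74e-05, adjusted p = 0.108 with an estimated correlation), with HSPB1 (2.80) and DNAJA1 (1.33). Ribosomal protein genes rose in 27 of 68 and fell in 1 with TMM scaling (the same over the list alone, adjusted p = 0.00546, adjusted p = 0.329 with an estimated correlation), but the list turns downward in FPKM. RPL17 (1.04) and RPS23 (0.98) lead it, and its call is lost without any 1 FCON replicate (up to 0.0949). The libraries that hold these rises are those with most rRNA and hardly any W counts. Lists not past the threshold held rises and falls in the following numbers: lipolysis 3 and 5 of 14, one-carbon metabolism 6 and 14 of 38, methylation enzymes 3 and 4 of 21, glucose 8 and 12 of 27, acute phase 11 and 7 of 26, unfolded protein response 4 and 6 of 20, clock 2 and 3 of 16. Cell type lists not past it held for cholangiocytes 2 and 2 of 7, stellate cells 5 and 1 of 13, endothelium 1 and 3 of 10, erythroid cells 0 and 0 of 8, heterophils 3 and 1 of 5, adipocytes 2 and 2 of 5. Those of the male tract held for spermatids 0 and 3 of 8, spermatogonia 1 and 2 of 8, testicular somatic cells 0 and 2 of 5, and genital tract 2 and 2 of 8. Median, mean and test differ in sign for cholangiocytes, heterophils, adipocytes, methylation enzymes and genital tract. Lists for exocrine pancreas, skeletal muscle, mitochondrially encoded genes and thrombocytes had fewer than 5 tested members.

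**Figure D2:**
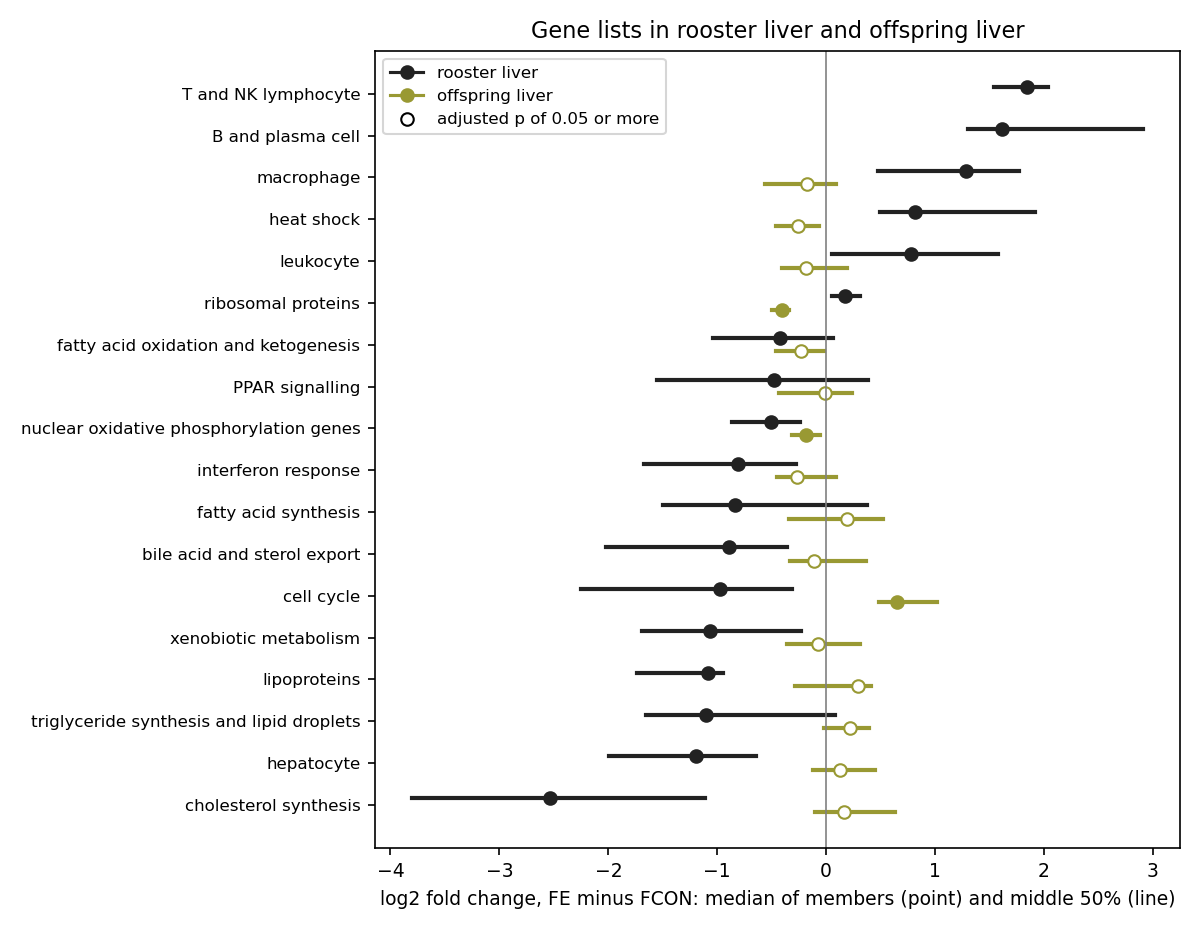
Median (point) and middle 50% (line) of the log2 fold changes, FE minus FCON, of the members of 18 gene lists that pass the threshold in rooster liver, in black, and the same lists in offspring liver, in olive. Open points have adjusted p of at least 0.05. The T and NK and B and plasma cell lists have fewer than 5 tested members in offspring. The rise of ribosomal proteins in rooster liver holds for TMM-scaled counts and turns downward in FPKM.

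In all, 4269 of 10291 tested genes were called in rooster liver, 2101 higher and 2168 lower in FE (5203 at unadjusted p below 0.05), 2270 of them at least 2-fold. The split between rises and falls depends on scaling: 49.2% of calls rise with TMM and 4.91% with limma on FPKM as deposited, where the median gene moves by -0.84 log2. Values of the groups did not overlap in 5947 genes (57.8%, where 10% would come by chance with 3 and 3 libraries), and 4257 calls are among them. Z genes account for 206 calls (158 higher, 48 lower, of 412 tested), W genes for 19 and all other genes for 4044. The calls numbered 2605, 2604 and 2560 without FCON replicate 1, 2 or 3.

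**Figure D3:**
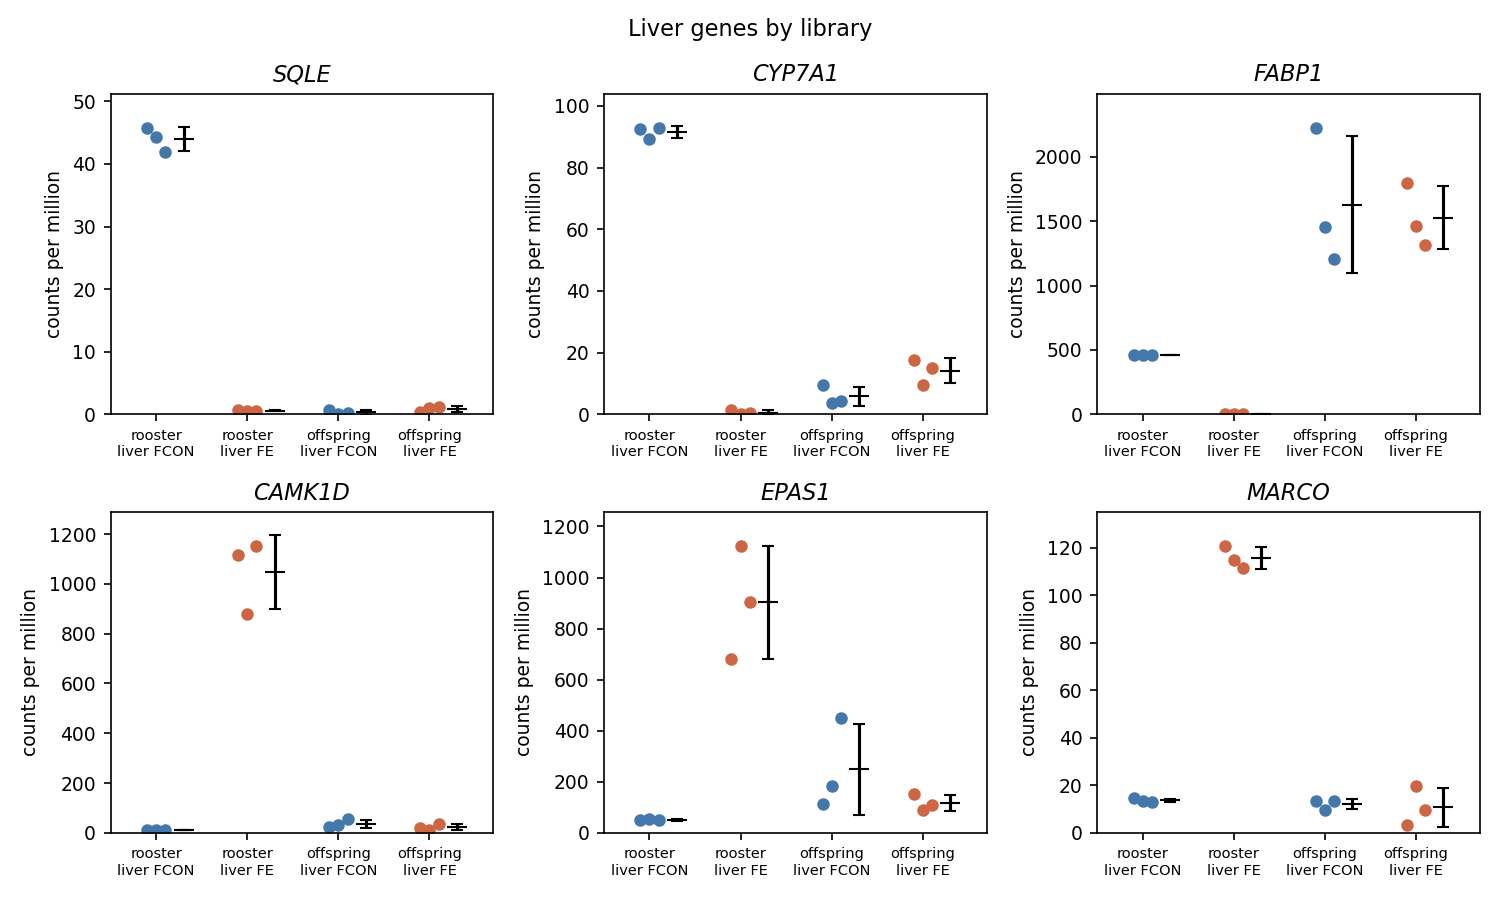
CPM (TMM over the 12 liver libraries) of SQLE, CYP7A1, FABP1, CAMK1D, EPAS1 and MARCO in each liver library, with mean ± SD of 3 libraries. The libraries labelled rooster FCON carry W counts and those labelled rooster FE hardly any.

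In liver of day-old offspring, no gene was called between the diets of the fathers. As whole lists relative to other genes, ribosomal protein, respiratory chain, one-carbon and heterophil genes fell and cell cycle genes rose in FE, but all 5 calls are lost with an estimated correlation (adjusted p = 0.851), and 7 of the 10 splits of these libraries give as many lists. MKI67, the marker of dividing cells, stood at 8.91 CPM in FCON and 30.0 in FE without passing the threshold by itself. None of the lipid lists passed, and none of the lipid genes that fell in the libraries labelled rooster FE was called here. Matched through synonyms too, cholesterol synthesis (upward, adjusted p = 0.0353) and fatty acid oxidation (downward, adjusted p = 0.0459) do pass. SQLE was at most 1.185 CPM in any chick library, so a fall of it could hardly show.

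Ribosomal protein genes had negative changes in 68 of 68 (median -0.40, adjusted p = 9.75e-12, 0 called over the list alone), led by RPS28 (-0.87) and RPL23A (-0.68). Cell cycle genes had positive changes in 31 of 33 (median 0.65, adjusted p = 3.23e-11, 3 called over the list alone), led by MKI67 (1.75) and the mitotic motor CENPE (1.53), but its call ends without both pools numbered 2, as do those of oxidative phosphorylation and one-carbon metabolism. Oxidative phosphorylation had negative changes in 40 of 47 (median -0.18, adjusted p = 0.0176, 0 over the list alone), with NDUFV1 (-0.58) and NDUFB8 (-0.67), and turns with quantile scaling (0.430). One-carbon metabolism had negative changes in 33 of 41 (median -0.21, adjusted p = 0.0184, 0 over the list alone), with the choline dehydrogenase CHDH (-1.83) and the folate enzyme MTHFS (-1.12). Heterophil genes had negative changes in 4 of 6 (median -1.18, adjusted p = 0.0424, 0 over the list alone), with the defensin AvBD1 (-2.98, a gene with near copies) and the cathelicidin CAMP (-1.81). Each of these 5 lists has adjusted p = 0.851 with an estimated correlation, and fry passes 0. One-carbon metabolism lost its call without FCON 3, FE 2 or FE 3 (up to 0.456), oxidative phosphorylation without FCON 3 or FE 3 (up to 0.233), and heterophils without FCON 2, FCON 3 or FE 1 (up to 0.356). The other 27 tested lists hold 0 called genes, with fatty acid oxidation (7 positive, 21 negative, adjusted p = 0.0535) and cholesterol synthesis (13 positive, 7 negative, 0.0719) nearest. Fatty acid synthesis (12 and 10, adjusted p = 0.482), triglycerides (10 and 4, 0.360), PPAR signalling (22 and 26, 0.639) and lipolysis (6 and 6, 0.914) were further off. Median, mean and test differ in sign for lipolysis, spermatids and spermatogonia.

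The genes with the smallest p on the positive side were the histone methyltransferase SMYD5 (gene 422951, chromosome 4, 89706416 to 89714666), SCAF11, INSIG1, MKI67 and ERI2. SMYD5 stood at 2.83 ± 0.599 and 18.3 ± 2.07 CPM (log2 2.69, adjusted p = 0.271), and INSIG1, which restrains sterol synthesis, at 6.00 ± 2.31 and 86.1 ± 77.1 (3.85, adjusted p = 0.462). SCAF11, a splicing factor (1.57), MKI67 (1.75) and the exonuclease ERI2 (2.58) have adjusted p from 0.441 to 0.510. On the negative side were the interferon-induced GBP4L (gene 415922, chromosome 12, 2699697 to 2704321, -1.51, adjusted p = 0.462), ANKS1A (-2.33), the glutaredoxin GLRX (-1.84), the sialic acid synthase NANS (-1.79) and NAT8 (-1.83).

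Of 14 panel genes tested 0 were called, with adjusted p from 0.701 to 0.993. SCD, PPARG and METTL4 were not tested. Only SREBF1 (1.80), DNMT1 (0.89) and MTR (0.87) had an unadjusted value below 0.05. The lipid genes ACACA (0.57), FASN (0.63), PPARA (-0.72), CPT1A (-0.03), LPL (0.57) and PNPLA2 (-0.55) were not called. Neither were the one-carbon genes BHMT (-0.09), SHMT1 (0.32) and MAT1A (0.06) nor N6AMT1 (0.16) and ALKBH1 (0.15).

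Among 9700 genes tested, edgeR called 0 (smallest adjusted p 0.271), with 679 at unadjusted p below 0.05. DESeq2 called 38 (17 higher, 21 lower) and limma on FPKM 0. Without FCON replicate 2 edgeR called 2 and without FE replicate 3 it called 1. Groups did not overlap in 1366 genes (14.1%, with 10% by chance). In counts simulated with the spread of these libraries the test found 34% of 4-fold changes, so smaller changes would be missed.

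In sperm, no gene was called between the diets. As lists relative to other genes, interferon response, ribosomal protein and cholesterol synthesis genes fell and spermatid and cell cycle genes rose in FE, but all 5 calls are lost with an estimated correlation (adjusted p = 0.865), and 9 of the 10 splits of these libraries give as many lists. DNAI2, an arm of the axonemal dynein, had log2 1.62 and the antiviral gene MX1 -1.74, neither past the threshold by itself.

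Interferon response had negative changes in 23 of 26 (median -0.51, adjusted p = 3.10e-04), with ZNFX1 (-1.81) and MX1 leading. Spermatid and sperm genes had positive changes in 24 of 30 (median 0.36, adjusted p = 3.10e-04), with DNAI2 and, against the list, SPATA17 (-1.28). Cell cycle genes had positive changes in 17 of 21 (median 0.60, adjusted p = 4.11e-04), with PRC1 (1.39) and RRM1 (0.68). Ribosomal protein genes had negative changes in 66 of 68 (median -0.40, adjusted p = 0.00140), with RPS24 (-0.74) and RPL14 (-0.60), and cholesterol synthesis in 20 of 20 (median -0.50, adjusted p = 0.00524), with INSIG1 (-1.65) and MSMO1 (-1.41). Each of these 5 lists has adjusted p = 0.865 with an estimated correlation, 0 members called over the list alone, and fry passes 0. Without FCON 1 the spermatid (0.175) and cell cycle (0.239) calls are lost, without FCON 3 the ribosomal one (0.249), and without FCON 1, FCON 3 or FE 2 that of cholesterol synthesis (up to 0.130). The other 22 tested lists hold 0 called genes, and median, mean and test differ in sign for one-carbon metabolism, glucose, heat shock, macrophages and leukocytes.

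On the positive side the smallest p belong to LINGO1 (2.31), RRNAD1 (2.37), the mitochondrial ribosome gene DAP3 (1.67), the phosphatase DUSP15 (2.02) and CTSA (1.09). On the negative side they belong to SPATA13 (-1.68), RHOA (-1.78, from 259 to 75.2 CPM), FAM107B (-1.46), MYH9 (-1.50) and MCF2 (-1.68). All have adjusted p = 0.902. Without FCON replicate 2, DAP3 (adjusted p = 0.0447), DUSP15 (0.0346), MCF2 (0.0439) and DNAI2 (0.0346) pass. Of 11 panel genes tested 0 were called (adjusted p from 0.902 to 0.972): ACACA (-0.39), FASN (-0.75), SCD (-0.95), SREBF1 (-0.38), PNPLA2 (-0.57), BHMT (-0.56), SHMT1 (0.66), MAT1A (-0.33), DNMT1 (-0.14), N6AMT1 (-0.58) and ALKBH1 (0.84).

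Among 8811 genes edgeR called 0 (smallest adjusted p 0.902), with 296 at unadjusted p below 0.05, DESeq2 called 0 and limma 1. Without FCON replicate 2 edgeR called 182, of which 179 were higher in FE. Groups did not overlap in 908 genes (10.3%, with 10% by chance). In counts simulated with the spread of the sperm libraries the test found 0% of 4-fold changes, so 0 calls say little about diet.

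Between generations, the diet effect in rooster liver differed from that in offspring liver in many genes, while 0 genes were called in offspring by themselves. The cholesterol synthesis list fell in the libraries labelled rooster FE and did not pass in offspring (adjusted p = 0.0719), where it passes upward with synonyms (0.0353). Bile acid and lipoprotein genes also fell in the libraries labelled rooster FE and did not pass in offspring. An estimated correlation ends the rooster calls of these 2 lists (adjusted p = 0.108 and 0.2). Most cholesterol synthesis genes were lower in FCON chicks than in the libraries labelled rooster FCON. SQLE stood at 0 to 0.705 CPM in offspring FCON and at 41.9 to 45.8 in rooster FCON, so its fall could hardly show in chicks. Expression in the FCON groups therefore enters the difference for cholesterol synthesis. The lists of ribosomal proteins and cell cycle genes had opposite signs in the 2 livers under TMM scaling, with calls that an estimated correlation ends. The W counts of the rooster groups enter every one of these differences. The nuclear rRNA share does too, and it differs in opposite directions. In rooster liver it was higher in FE (45.9 ± 13.9%) than in FCON (6.43 ± 3.02%). In offspring liver its mean was lower in FE (13 ± 7.89%) than in FCON (24.5 ± 7.02%), with overlap between libraries. Opposite signs in these livers therefore do not by themselves show opposite effects of the diet.

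Of 11002 genes 2054 were called for a difference of diet effects (929 with a higher effect in the libraries labelled rooster, 1125 lower), with 3779 at unadjusted p below 0.05 and 1967 at least 2-fold. The share with a higher effect is 45.2% with TMM scaling and 3.57% with limma on FPKM, where the median gene moves by -1.15 log2. Without rooster FCON replicate 1, 2 or 3 the count was 1251, 1248 and 1244. Across 9243 genes the effects in the 2 livers correlated at r = -0.36 (rank correlation -0.38, 37% with the same sign, called or not), with genes not being independent replicates, and at -0.14 without the expression filter. For rooster liver and sperm r was -0.02 over 7450 genes, and for offspring liver and sperm -0.10 over 7319. In all, 15 of 36 lists passed, 5 with a higher and 10 with a lower effect in the libraries labelled rooster. Of 100 splits, the real one among them, 11 gave at least as many lists, so this number does not stand out from false groups. Median, mean and test differ in sign for one-carbon metabolism, glucose, clock, B and plasma cells and adipocytes.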

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

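The 3 tests of W genes, the test of sex chromosome dosage and the test of sex or origin against diet were chosen only after the results had been seen. The thinning, the rRNA slopes and the splits into false groups were chosen before.

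Hens carry a W and roosters do not, but the libraries labelled rooster FCON average 1065 CPM of W genes, and none was below 1015. Reads of the Z copies cannot account for this, because in FE the Z copy of ATP5A1W has 16301 counts and ATP5A1W 0, a W to Z ratio of at most 0.0255% of that in FCON (41526 and 57491). Relative to autosomal genes, Z genes differ between FCON and FE by -0.5121 log2 (SE 0.0492). An equal mix of hen and rooster RNA would give -0.4150 if Z genes had no dosage compensation. Compensation, not measured here, would make a mix differ less. The value lies beyond this bound, but by less than 2 SE, so a minor share of hen RNA stays open. RNA of female birds only could also give such a difference of Z genes. The W-rich offspring pools numbered 2 stood at -0.4439 (FCON) and -0.3035 (FE) for Z genes, and rooster FCON at -0.3313 to -0.3189. For ATP5A1W, rooster FCON (353 to 385.3 CPM without rRNA) was near these pools (396.1 and 377.8). HINTW was lower in rooster FCON (252.7 to 259.3) than in them (528.3 and 457.2). Whether these pools hold only females is not known, so they do not set a mix and female birds apart. VTG1 (0.253), VTG2 (0.0914) and APOV1 (0.489 CPM without rRNA), which livers of laying hens make in bulk, were near 0 in the libraries labelled rooster FCON. That goes against hens in lay. ALB (74960 ± 563 CPM without rRNA) and TTR (1491 ± 59.3) were higher in these libraries than in rooster FE (17000 ± 4087 and 683 ± 208). This argues against a tissue other than liver. Exchange of labels, of liver samples or of libraries could each be behind the W counts, and the value of 1015 does not tell which.

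Between rooster livers 4269 genes were called, and 94.7% of the calls lie outside Z and W. Dosage of the called genes themselves therefore cannot account for most calls. Only 412 of the 10291 tested genes lie on Z, though, so such a share would come with many causes. Effects of Z or W genes on other genes stay open. Thinning every library to the same number of counts without rRNA, 7.73 M (mega), kept 92.5% of the calls (3939 of 4260), so unequal depth and the counts that rRNA genes took are not their only source, but RNA quality or poly(A) capture, which an rRNA share of 45.9% against 6.43% may reflect, lies on the same split and stays open. Of the 10 splits of these libraries only 1, the real one, gave so many genes, against 1 gene in the highest other, and likewise 18 lists against 12; with 10 splits a share under 0.05 is out of reach. Diet, sex and origin of the birds lie on the same split, with at least 1015 CPM of W genes in each FCON library, so these comparisons cannot tell them apart.

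The estimated effects of the diet in rooster and offspring liver correlated at r = -0.36 (-0.1415 without the expression filter), with 0 genes called in offspring. The mean nuclear rRNA share differs in opposite directions too. It was higher in FE in rooster liver (45.9% against 6.43%) and lower in FE in offspring liver (13% against 24.5%). If the rRNA share of a library bent its values, genes should follow it within groups. Such slopes within offspring groups correlate with the rooster effects at 0.1551. Of 36 orders of the shares 5, the real one among them, gave a value at least this high. Shuffled shares span -0.2128 to 0.2061, so this test cannot tell whether the rRNA share plays a part. Slopes within rooster groups against offspring effects gave -0.0242, but its bound of -0.2 was badly set, because shuffled shares span only -0.0506 to 0.0519 and could never have reached it. Of the 100 splits of both livers 1, the real one, gave a correlation this large (0.3591 in size, highest other 0.3233), and of the 100 taken for genes and lists 1 gave 2054 genes (highest other 1751), while 11 gave 15 or more lists (highest other 19). The false splits among them with rooster livers in their true groups still gave 332 to 1751 genes, so the rooster difference by itself could carry most of this result. For lists, 11 of 100 splits is a share above 0.05, and some of those splits mix the rooster groups. The number of lists that pass therefore does not set the real groups apart from false ones. The splits for the correlation cross 10 splits of each liver, so most of them mix the rooster groups. With rooster livers in their true groups only 10 splits exist, and a share under 0.05 is out of reach.

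In offspring liver 0 genes were called and 5 lists passed, and 7 of the 10 splits gave as many lists (highest other 14) and 10 as many genes (highest other 1). In sperm 9 of the 10 splits gave as many lists as the real 5 (highest other 11) and 10 as many genes (highest other 1). The sperm splits that part all 3 numbered pairs gave 4, 7 and 6 lists and 0 genes. The lists of both comparisons may therefore reflect which libraries happen to lie together, since 7 and 9 of 10 splits do as well.

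The single genes that the naming rule, which ranks by log2(FPKM + 1), takes for the difference of effects, rooster minus offspring, are the kinase CAMK1D (7.20, adjusted p = 4.34e-05), COTL1 (5.30, 4.34e-05), CTSD (5.34, 3.71e-04), EPAS1 (5.25, 4.30e-04), LRR1 (4.96, 0.00444), AvBD1 (8.28, 0.0317), MIR1557 (7.03, 0.0315) and MT3 (4.79, 0.0259) on the higher side. On the lower side are CYP7A1 (-8.77, adjusted p = 3.96e-04), FABP1 (-7.57, 9.62e-05), LYG2 (-7.20, 1.65e-04), HTD2 (-6.72, 0.0335), CYP8B1 (-6.35, 1.88e-04), the betaine transporter SLC6A12 (-5.76, 6.10e-04), the bile acid carrier SLCO1B3 (-5.44, 3.77e-04) and MIR3064 (-3.89, 0.0222). Calls were lost for MIR1557 without any 1 rooster FCON, rooster FE 1 or offspring FE 1 (up to 0.0862), and for MIR3064 without rooster FE 3 (0.0550). They were lost for AvBD1 without rooster FCON 1, FCON 2, FE 2, FE 3 or any 1 offspring FE (up to 0.0716). MT3 lost its call without any 1 rooster FCON, offspring FCON 1 or offspring FE 3 (up to 0.0619), and HTD2 without any 1 rooster FCON, rooster FE 1, rooster FE 3 or offspring FE 3 (up to 0.0701). In all of these the libraries labelled rooster FCON carry W counts and those labelled rooster FE hardly any, while in each offspring group only pool 2 does.

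Of 15 panel genes tested 6 were called. SCD, which was not tested in offspring by itself, has no usable estimate here (SE 3651 log2). SREBF1 (-3.63, adjusted p = 0.00466), CPT1A (-2.03, 0.0444), LPL (-3.09, 0.0193), BHMT (-1.86, 0.0247) and DNMT1 (-2.45, 6.84e-04) had lower effects in the libraries labelled rooster, and PNPLA2 (1.89, 0.0123) a higher one. CPT1A lost its call without any 1 library except rooster FE 1 and offspring FCON 1 (up to 0.1), LPL without rooster FE 3 (0.0507), and BHMT without any 1 rooster FCON, rooster FE 2 or rooster FE 3 (up to 0.0541).

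Lists with a lower effect in the libraries labelled rooster were cholesterol synthesis (16 lower and 0 higher of 22, adjusted p = 2.85e-16, and adjusted p = 4.56e-04 with an estimated correlation), cell cycle (13 and 0 of 33, 7.13e-08, estimated 0.298), hepatocytes (10 and 1 of 18, 2.61e-05, estimated 0.462), bile acids (5 and 0 of 15, 5.82e-04, estimated 0.118) and lipoproteins (5 and 1 of 12, 0.00270, estimated 0.462). The others were triglycerides (6 and 0 of 14, adjusted p = 0.00270, estimated 0.120), xenobiotic metabolism (14 and 3 of 35, 0.00896, estimated 0.118), PPAR signalling (14 and 6 of 50, 0.0175, estimated 0.118), fatty acid synthesis (8 and 0 of 25, 0.0260, estimated 0.120) and interferon response (8 and 1 of 32, 0.0484, estimated 0.583). Heat shock (11 higher and 0 lower of 22, adjusted p = 2.61e-06, estimated 0.241), macrophages (5 and 0 of 14, 5.30e-05, estimated 0.462), T and NK cells (5 and 0 of 10, 0.00335, estimated 0.118) and leukocytes (2 and 0 of 11, 0.00896, estimated 0.583) had a higher effect. So had ribosomal proteins (17 and 0 of 68, adjusted p = 7.13e-08, estimated 0.462), but only with TMM and related scalings, not in FPKM or with total counts. Fatty acid synthesis lost its call without rooster FE 2 (0.0581), interferon response without rooster FE 1, rooster FE 3, offspring FCON 1, offspring FE 2 or offspring FE 3 (up to 0.176), and xenobiotic metabolism and leukocytes without offspring FCON 1 (up to 0.0598). Of 18 other settings, 9 ended the call of PPAR signalling (adjusted p up to 0.298), 8 that of ribosomal proteins (up to 0.909), 7 that of fatty acid synthesis (up to 0.264), 6 that of triglycerides (up to 0.120), 6 that of interferon response (up to 0.583) and 2 that of leukocytes (up to 0.583). In limma on FPKM as deposited the values were 0.259 for PPAR signalling, 0.183 for fatty acid synthesis, 0.0534 for triglycerides and 0.272 for ribosomal proteins. The difference for cholesterol synthesis includes SQLE, which was near 0 in chicks of both groups.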

How the results depend on the processing

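In rooster liver the 4269 calls became 6228 with limma on FPKM as deposited (306 higher, 2470 shared with the same direction), 7184 with FPKM set to the same sum in every library, called equal FPKM sums below (296 higher, 4.12%, median gene -0.99), 5221 with total counts (5.42% higher, median gene -0.92), 4963 with DESeq2, 2448 with unadjusted p and 2-fold, and 896 in a fit of all 18 libraries. They were 4279 without rRNA genes and 4048 without Z and W genes. Leaving out 1 library gave 2560 to 5161.

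In offspring liver the 0 calls became 1 with a pseudocount of 0.1, 1 without the expression filter, 3 with equal FPKM sums, 2 without a trend, 419 with unadjusted p and 2-fold, 2 with all 18 libraries, 38 with DESeq2 and 1 without both pools numbered 2. Leaving out 1 library gave 0 to 2. In sperm the 0 calls became 1 with limma, 1 with robust limma, 273 with unadjusted p and 2-fold, 8 with all 18 libraries, and 0 to 182 with 1 library left out.

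For the difference of diet effects the 2054 calls became 5776 with limma on FPKM (206 higher), 5522 with a pseudocount of 0.1, 7042 with equal FPKM sums, 5757 without a trend, 5760 with robust limma, 3193 with unadjusted p and 2-fold, 654 with all 18 libraries, 4882 with total counts, 2819 with DESeq2, 1773 without both pools numbered 2, 2048 without rRNA genes and 2031 without Z and W genes. Leaving out 1 library gave 1244 to 2192. Control livers by age had 3037 calls, 4121 with limma on FPKM, 5929 with equal FPKM sums (6.11% higher, median gene -0.81), and 783 to 4087 with 1 library left out. Taken between the FE groups the same comparison called 2700 genes, 858 of them shared.

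The correlation of the diet effects, -0.3591, was -0.1415 without the expression filter, -0.4177 at 5 FPKM, -0.4075 with quantile scaling, -0.1656 with all 18 libraries and -0.3467 without both pools numbered 2. Leaving out 1 library gave -0.3796 to -0.2473 (SD 0.0351), the last without offspring FCON 3.

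With number as a block, as in a paired design, the calls were 3442 in rooster liver, 0 in offspring, 0 in sperm, 1210 for the difference of effects and 2026 by age, the lists 18, 4, 5, 15 and 13, and the correlation -0.3549. Residuals of libraries with the same number correlated at -0.0164, 0.0027 and 0.0124 in rooster liver, -0.0787, 0.0274 and -0.181 in offspring, and 0.0268, -0.0162 and 0.0149 by age, so there numbers do not pair. In the block fit offspring CPT1A was 0.27 and MAT1A -0.0083, and sperm BHMT 0.0862, against the sign without the block.

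An estimated correlation left 3 lists past the threshold in rooster liver, 0 in offspring, 0 in sperm, 1 for the difference and 2 by age, where the preset one gave 18, 5, 5, 15 and 12. fry passed 30, 0, 0, 19 and 15. At 5 FPKM offspring had 3 lists and sperm 3, and with all 18 libraries offspring had 8. Leaving out 1 library gave 16 to 17 lists in rooster liver, 3 to 7 in offspring, 4 to 8 in sperm, 12 to 16 for the difference and 12 to 14 by age. With synonyms offspring has 7 lists.

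Rooster calls ended for PPAR signalling under 5 settings of limma on FPKM, for triglycerides, B and plasma cells and leukocytes with all 18 libraries, for leukocytes at 5 FPKM, for fatty acid synthesis with equal FPKM sums and for cell cycle with total counts. Those of offspring ended for one-carbon metabolism at 5 FPKM, with equal FPKM sums, with quantile scaling and without both pools numbered 2, and for oxidative phosphorylation with most limma scalings, total counts and without those pools. Offspring heterophils ended with the block and all 18 libraries, cell cycle without the pools numbered 2, and ribosomal proteins with quantile scaling, which ended them in sperm too. Sperm interferon and cell cycle calls ended at 5 FPKM, and that of cholesterol synthesis with all 18 libraries.

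Lists that turned: the rise of ribosomal proteins in rooster liver became a fall with adjusted p = 0.952 in FPKM as deposited (also without a trend and with robust limma), 0.642 with a pseudocount of 0.1 and 0.271 with equal FPKM sums, where RPL17 was -0.0360 and RPS23 -0.10. Offspring oxidative phosphorylation turned with quantile scaling (0.430). By age, the FE groups ended the calls of cholesterol synthesis (0.966) and fatty acid synthesis (0.834) and turned triglycerides (0.542), heat shock (0.0655), xenobiotic metabolism (0.468) and hepatocytes (0.0699), as well as GLRX (-0.76), PDSS2 (-1.19) and LYG2 (0.36).

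Panel genes that turned in rooster liver were ACACA (-0.0621 with equal FPKM sums, -0.17 with total counts), MAT1A (-0.17 in FPKM as deposited, without a trend and with robust limma, -0.18 with a pseudocount of 0.1, -0.28 with equal FPKM sums) and ALKBH1 (-0.60 in FPKM as deposited, without a trend and with robust limma, -0.77 with the pseudocount, -0.76 with equal FPKM sums, where it is called lower at adjusted p = 0.0408, -0.69 with total counts). With 1 library left out PPARA ranged from -0.84 to 0.16 and N6AMT1 reached 0.14.

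In offspring CPT1A turned to 0.57 in FPKM as deposited, without a trend and with robust limma, 0.66 with the pseudocount, 0.0413 at 5 FPKM, 0.24 with median-of-ratios FPKM, 0.69 with equal FPKM sums, 0.18 with quantile scaling, 0.32 with total counts and ranged from -0.41 to 0.85 with 1 library left out. BHMT turned to 0.23 in FPKM as deposited, without a trend, with robust limma and with the pseudocount, 0.33 with equal FPKM sums, 0.12 with quantile scaling, 0.32 with total counts, 0.22 without both pools numbered 2, and ranged from -0.67 to 0.18 with 1 library left out. N6AMT1 was -0.23 without both pools numbered 2. With 1 library left out MAT1A reached -0.33, while SHMT1 ranged from -0.19 to 0.86, N6AMT1 from -0.11 to 0.52 and ALKBH1 from -0.0134 to 0.37.

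In sperm DNMT1 turned to 0.0155 with quantile scaling and 0.0562 with total counts. With 1 library left out ACACA ranged from -0.59 to 0.19, SREBF1 from -0.73 to 0.0570, BHMT from -0.9999 to 1.04, MAT1A from -0.67 to 0.35 and DNMT1 from -0.32 to 0.48.

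Counted over named genes and settings, the result stayed in 955 cases in rooster liver, 495 in offspring, 465 in sperm, 360 for the difference and 264 by age. It weakened in 54, 0, 0, 33 and 4, grew stronger in 31, 29, 13, 0 and 0, and turned in 15, 20, 3, 0 and 3. For lists it stayed in 270, 61, 71, 223 and 169, weakened in 28, 21, 9, 46 and 29, and turned in 5, 1, 0, 0 and 4. For genes in offspring and sperm, where none is called, staying means only the same sign and still no call.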

Other observations

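Between FCON livers of day-old offspring and the libraries labelled rooster FCON at 35 weeks, interferon response and cholesterol synthesis genes were lower in the day-old chicks, but between the FE groups the cholesterol call is gone (adjusted p = 0.966). Cell cycle, ribosomal protein and oxidative phosphorylation lists were higher, with calls that an estimated correlation ends (adjusted p = 0.335, 0.327 and 0.303). PIGR, which carries antibodies into bile, had 0 counts in the chicks and 483 CPM in the libraries labelled rooster FCON, at least 9810-fold lower. HPS5, a serum amyloid A gene by its reference symbol, stood at 2182 in chicks and 123 in those labelled rooster FCON. Age and pooling both lie on this split. So does the nuclear rRNA share, at 16.4 to 29.1% in offspring FCON and 3.02 to 8.75% in rooster FCON, and mitochondrial rRNA (means 5.65% and 0.57%). Sex as read from W genes lies partly on this split: all 3 libraries labelled rooster FCON carry W counts (1015 to 1117 CPM), and of the chick pools only number 2 does (963).

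Interferon response was lower in 29 of 32 genes (adjusted p = 8.13e-27, and 0.0290 with an estimated correlation) and cholesterol synthesis in 18 of 22 (5.22e-26, estimated 0.00964, and 0.966 between the FE groups). Fatty acid synthesis was lower in 10 of 25 (adjusted p = 0.00461, estimated 0.244, and 0.834 between the FE groups), triglycerides in 5 of 13 (0.00536, estimated 0.303, and 0.0637 without offspring FCON 3; between the FE groups turned, 0.542), xenobiotic metabolism in 11 of 35 (0.0296, estimated 0.335, and 0.159 without offspring FCON 1; turned, 0.468) and hepatocyte genes in 7 of 18 (0.02, estimated 0.783; turned, 0.0699). T and NK genes were lower in 4 of 5 (adjusted p = 2.62e-05, estimated 0.244) and leukocyte genes in 3 of 11 (0.00575, estimated 0.493). Higher in chicks were cell cycle genes in 25 of 26 (adjusted p = 2.29e-14, estimated 0.335), ribosomal proteins with TMM scaling in 61 of 68 (3.58e-21, estimated 0.327), oxidative phosphorylation in 30 of 48 (9.92e-08, estimated 0.303) and heat shock in 11 of 22 (0.00461, estimated 0.666; turned between the FE groups, 0.0655). Median, mean and test differ in sign for endothelium, heterophils, spermatogonia and glucose.

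Single genes higher in chicks were GLRX (3.98, from 5.71 to 90 CPM), HPS5 (4.15), S100A9 (4.11), RP11-400G3.5 (3.77), PDSS2 (3.76), the creatine enzyme GATM (3.62), the centromere histone CENPA (3.61) and MXD3 (3.48), with adjusted p from 0.00178 to 0.0116. GATM (up to 0.0580) and RP11-400G3.5 (up to 0.0508) lost their calls without any 1 rooster FCON library. Between the FE groups GLRX (-0.76) and PDSS2 (-1.19) turn, as does LYG2 (0.36) among the genes lower in chicks. Lower were PIGR, IFI6 (-6.94), LYG2 (-6.81), the desaturase FADS2 (-6.82, 5.14 in chicks and 578 in the libraries labelled rooster FCON), C4A (-6.27), OASL (-5.05), CD74 (-4.71) and INSIG1 (-5.28, 6.12 and 237), with adjusted p from 4.36e-04 to 0.00371. In all, 3037 of 10339 genes were called, 1609 higher and 1428 lower (4413 at unadjusted p below 0.05). The share of higher calls was 53% with TMM scaling and 15.7% with limma on FPKM, where the median gene moves by -0.46. Groups did not overlap in 5523 genes (53.4%, with 10% by chance). Without rooster FCON 1, 2 or 3 the calls numbered 788, 810 and 783. The real split gave 3037 genes against 1 in the highest other and 12 lists against 18, and 4 of 10 splits gave as many lists as the real one.

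A single unnamed gene, LOC112530621, took 8.12% to 45.3% of all counts in sperm libraries (34.4 ± 10.9% in FCON, 28.7 ± 18.3% in FE). In offspring livers it took 0.0310 ± 0.0272% in FCON and 0.00359 ± 0.00437% in FE.

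The egg yolk genes VTG1 and VTG2, which livers of laying hens make in bulk, stood at 0.253 and 0.0914 CPM without rRNA in the libraries labelled rooster FCON. ALB, the main plasma protein, took 74960 ± 563 CPM in them and 17000 ± 4087 in rooster FE. The genes with at least 1 FPKM numbered 10360 and 8547.

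Within groups the spread between libraries was smallest in rooster FCON, with a biological coefficient of variation of 0.137, against 0.243 in rooster FE, 0.360 and 0.325 in offspring and 0.479 and 0.381 in sperm. The 3 libraries of rooster FCON exceeded pure sampling noise 6.44-fold to 6.86-fold, where pairs of other groups reached 13.3-fold to 109-fold, and 0 pairs were identical. The small spread of rooster FCON enters the p-values of every comparison that uses these libraries. That the 3 rooster FCON libraries are separate birds rests on their labels alone and was not tested, and those p-values depend on it. The first axis of a principal component analysis held 36% of liver variance and the second 22.6%, and in sperm they held 48.5% and 24.6%.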
